A study of Homo sapiens with 12 samples.

How the data were processed

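Messenger RNA levels were measured on 12 one-colour Agilent arrays. The RNA came from H2009 and H2135, established human non-small cell lung cancer cell lines. Each line had received either an empty vector (mock) or a plasmid carrying the gene for β2-microglobulin (wtB2M), and each of the 4 groups held 3 arrays. Per the labels, the cells grew in HITES medium, a defined medium for lung cancer cells, with 5% fetal bovine serum. Total RNA was extracted with Trizol, and 45 ng of it was amplified and labelled with Cy3 by the Low Input QuickAmp method. The labels do not say whether the replicates were separate cultures or separate transductions. The p-values therefore measure the spread between these arrays, which may be technical.

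The authors deposited the scanner software's output for each array and a table of normalized values. Per the file headers, Agilent Feature Extraction 10.7.3.1 produced the intensity values by subtracting background and removing spatial trends from the Cy3 signal, with a small substitute value for spots not above background. The headers record no normalization between arrays for these intensities. The deposited values are on a log2 scale, and their 12 columns have nearly the same distribution, with medians from 6.22 to 6.28. The method behind them was not stated, and they followed the scanner intensities of the same array with a correlation across probes of 0.978 to 0.987. They served only as an alternative. Each array carried 62976 spots, of which 58717 were not controls and belonged to 50599 probes. No spot was saturated. Between 50.4% and 58.5% of probes were well above background on 11 arrays, and 70.6% on H2135 mock replicate 3. Each 75th percentile signal lay between 642 and 1182 intensity units. The number of arrays limits the precision.

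Spots that the scanner software marked as outliers were left out, the log2 intensities of the spots of a probe were averaged, and each array's 75th percentile was subtracted. A level of 0 is therefore the 75th percentile of the array. A probe was kept if it was well above background on at least 3 of the 12 arrays, which left 30909 probes, and the probe with the highest mean stood for its gene. Probes were named through the RefSeq gene names of assembly GRCh38.p14, used for names only: 28174 by RefSeq accession, 2618 by symbol and 620 by an older symbol, while 19187 kept the name in the files. Probe coordinates are those of the files, on hg19. In all 23085 genes were tested.

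A limma model (version 3.58.1, R 4.3.3, with the packages data.table, version 1.17.8, and jsonlite, version 2.0.0) was fitted to all 4 groups at once, with 8 residual degrees of freedom and 9.86 after moderation. The contrasts were wtB2M minus mock in each line, the difference between these (H2135 minus H2009), their average, and H2135 mock minus H2009 mock. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Genes called in both lines with the same sign were counted as well. All p-values are two-sided. For the B2M probe, an exact permutation test was run within each line, where 20 assignments of the arrays allow no p below 0.1, and another with arrays exchanged within both lines, where 400 assignments allow no p below 0.005. Where no array of a group was well above background, a fold was given only as a bound: the level there was set to the array's lowest signal well above background, or to the measured value if that was higher. Genes without such a bound, or at background in both groups, were set to 0 where a median at the bound is given.

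Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, and again with the correlation estimated from the arrays. The directional test fry, which asks whether a list's genes move one way and not whether they move more than other genes, was run as an alternative. The 25 lists held 577 genes, of which 515 were tested. They were MHC class I presentation, MHC class I-like partners of B2M, MHC class II presentation, the type I interferon response, the interferon gamma response, NF-kB targets and inflammatory cytokines, NK cell and checkpoint ligands, the unfolded protein response, the heat shock response, G2/M and mitosis, DNA replication, p53 targets, cholesterol biosynthesis, hypoxia and glycolysis, oxidative phosphorylation, NRF2 targets, iron handling, immediate-early and MAPK targets, epithelial genes, mesenchymal and TGF-beta targets, lung differentiation, cancer-testis antigens, markers of blood cells, markers of stroma and endothelium, and reference genes. A list needed at least 5 measured members, so the class I-like partners, with 3, were left out of the list test, and 70 genes with a missing value were left out of every list test. A list's shift is the median log2 change of its members minus that of all genes.

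The groups, contrasts, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named B2M and heavy-chain genes, among them HLA-B, HLA-C and HLA-E, in each comparison of wtB2M with mock. Per line it named the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, leaving out names that are only a clone or locus code, XIST and Y-linked genes. It also named up to 4 called members per list, up to 10 genes called in both lines with the same sign and up to 5 with opposite signs, the 10 smallest p-values for the difference between lines, the 5 largest differences each way between the mock arrays, and, where fewer than 5 genes were called, the 5 with the smallest p. Members of a list could be named where the list is described. Not every gene that the rule named is given.

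The alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the array median, no filter or a filter at all 12 arrays, the deposited value table, the replicate number or the slide as a block, the mean of a gene's probes, a moderated variance with a trend and robust fit, array weights, only the groups of a comparison, an added minimum change of 1 on the log2 scale, and each array left out in turn. All arrays carried the same scan date, so no block of dates was run. The code was tested on simulated data made from these arrays. In the H2135 contrast, over 23015 genes, it recovered 90.3% of genes given a log2 change of 2, 48.3% at 1 and 15.4% at 0.5, with 8 false calls. In the H2009 contrast, over as many genes, it recovered 82.6%, 54.2% and 5.1%, with 4 false calls. With DNA replication as the only list shifted, by 0.3, camera also called 2 other lists in H2009 and 0 in H2135. The simulated noise was independent between genes, so correlated genes were not simulated. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15, and the probe was translated with Biopython 1.88.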

Results

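The arrays were made to find which transcripts change when β2-microglobulin is restored in lung cancer lines deficient in it. β2-microglobulin, encoded by B2M, is the light chain that MHC class I heavy chains need to fold and reach the cell surface. The 12 arrays separated by line first: the first principal component held 83.2% of the variance and parted H2009 from H2135, and the second held 5.6%. Within the groups, replicate arrays correlated across genes at 0.978 to 0.993. The arrays lay on 5 slides. Arrays of different groups that shared a slide had a median residual correlation of 0.107 across genes, against -0.032 for arrays on different slides, so values from within a slide stand beside the pooled ones.

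B2M mRNA was above background on every mock array of both lines, and wtB2M arrays carried more of it. The arrays do not tell whether that mRNA gives a functional protein. In H2135 the B2M level was 3.09 ± 0.11 (SD, n = 3, log2 over the array's 75th percentile) with the empty vector and 5.28 ± 0.44 with wtB2M. The rise was 2.19 on the log2 scale with a standard error of 0.20, which is 4.55-fold (limma adjusted p = 0.0110). With the slide as a fixed block it was 2.01 and did not pass (limma adjusted p = 0.178). In H2009 the level was 5.50 ± 0.17 on mock arrays and 5.98 ± 0.16 on wtB2M arrays (SD, n = 3). That difference of 0.48 with a standard error of 0.20 did not pass the test (limma adjusted p = 0.723). The wtB2M level in H2135 lay 0.22 below the mock level of H2009.

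The probe, A_23_P37441, lies at 45007773 to 45007832 of chromosome 15 on hg19 and was printed in 10 spots per array. Its sequence, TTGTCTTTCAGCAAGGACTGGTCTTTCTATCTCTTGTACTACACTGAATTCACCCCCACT, reads in its frame 1 as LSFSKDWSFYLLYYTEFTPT, a stretch of the mature β2-microglobulin protein. It is therefore exonic coding sequence, outside the untranslated regions, and transcripts of the cell's own gene and of a plasmid with that coding sequence bind it alike. All 3 wtB2M arrays lay above all 3 mock arrays in each line, and the exact permutation test gave p = 0.1 in each line, the smallest it can give. With arrays exchanged within both lines the exact permutation p was 0.005, also the smallest possible. Within a single slide the B2M difference was 2.26 in H2135 (mock replicate 1, wtB2M replicate 3) and 0.32 in H2009 (mock replicate 1, wtB2M replicate 3).

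The heavy-chain genes HLA-B, HLA-C and HLA-E, whose products pair with β2-microglobulin, did not pass the test in either line. Their log2 differences between wtB2M and mock lay between -0.14 for HLA-E and 0.21 for HLA-C in H2009 and between -0.046 for HLA-E and 0.069 for HLA-C in H2135. Standard errors ran from 0.12 for HLA-E to 0.15 for HLA-C. HLA-E in H2135 lay at the median of all genes, which was also -0.046, and both stood at 0.41 with arrays centred on their median. HLA-B stood at -0.040 in H2135 after quantile normalization, and none was called under these scalings. The class I-like partners MR1 and FCGRT differed by 0.0037 and 0.047 in H2135 and by -0.077 and -0.051 in H2009. HFE, an iron regulator that also binds β2-microglobulin, differed by -0.25 in H2009 and was above background on 1 array of H2135, and none of the 3 passed.

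**Figure D1:**
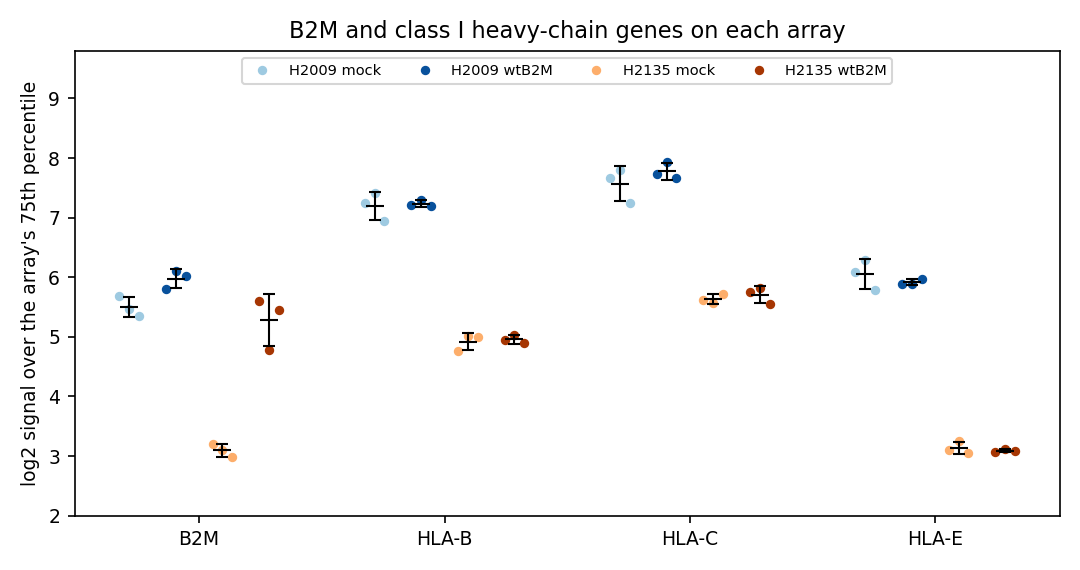
Log2 signal over the array's 75th percentile (vertical axis) of B2M, HLA-B, HLA-C and HLA-E, with 1 point per array and the mean and SD of the 3 arrays of each group. The H2135 B2M level goes from a mean of 3.09 on mock arrays to 5.28 on wtB2M arrays, while the 3 heavy-chain genes differ by at most 0.21 between wtB2M and mock in either line.

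In H2009, wtB2M arrays showed a small upward shift of mitotic genes and no single gene past the threshold. The G2/M and mitosis list, genes of spindle and chromosome segregation, was shifted by 0.22 on the log2 scale relative to all genes (camera adjusted p = 3.06e-05), with 27 of its 30 members above the median of all genes. With an estimated correlation no list was called in H2009, and the adjusted p was 0.925 for this list and for the other 2 called here. Without H2009 mock replicate 2 the G2/M shift was 0.050 (adjusted p = 0.0155). CENPF, a kinetochore protein, differed by 0.51 with a standard error of 0.23, DLGAP5, a spindle protein, by 0.44 with 0.21, and MKI67, the proliferation marker, by 0.33 with 0.14. The cholesterol biosynthesis list was shifted by 0.088 (camera adjusted p = 0.0352), with 18 of 22 members above the median of all genes. Without H2009 wtB2M replicate 3 it was 0.027 (adjusted p = 0.652), and without H2009 mock replicate 3 it was 0.055 (adjusted p = 0.385). The call also ended at about the same size without H2009 mock replicate 1, at 0.082 (adjusted p = 0.301), and without H2135 mock replicate 2, at 0.088 (adjusted p = 0.053). In that list IDI1, an isoprenoid isomerase, differed by 0.28 and HMGCS1, which makes the HMG-CoA of the mevalonate pathway, by 0.25.

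The immediate-early and MAPK list was shifted the other way in H2009, by -0.093 (camera adjusted p = 0.0352), and 7 of its 28 members lay above the median of all genes. Without H2009 mock replicate 1 it was -0.016 (adjusted p = 0.525). Without 4 other arrays in turn the call ended at shifts of -0.070 to -0.10, and with median centring (adjusted p = 0.423) and a replicate block (adjusted p = 0.113) it ended at an unchanged -0.093. EGR2, an immediate-early transcription factor, differed by -0.72 with a standard error of 0.22, JUN by -0.38 with 0.11, and HBEGF, an EGF receptor ligand, by -0.36 with 0.10. The single slide with both H2009 groups gave shifts of 0.066 for the G2/M list, 0.25 for the cholesterol list and -0.14 for the immediate-early and MAPK list. In a fit with the slide as a fixed block, the shifts were 0.25 for G2/M (adjusted p = 3.59e-07), 0.18 for cholesterol (adjusted p = 0.000439) and -0.057 for immediate-early and MAPK, whose adjusted p rose to 0.157. After quantile normalization the cholesterol list stood at 0.046 and lost its call (adjusted p = 0.194).

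The other 21 lists were not called in H2009, with adjusted p from 0.112 upwards. NF-kB targets stood at -0.13, and at -0.20 with the slide as a fixed block, where they were called (adjusted p = 0.00576). Mesenchymal and TGF-beta targets stood at -0.085, lung differentiation at -0.086, and the markers of blood cells at -0.14. Cancer-testis antigens stood at -0.032, although camera's mean-based test pointed up, and the median and the test also differed in sign for MHC class II presentation at 0.0014 and the interferon gamma response at 0.0085. MHC class I presentation stood at 0.051, the type I interferon response at 0.036, NK cell and checkpoint ligands at -0.016, the unfolded protein response at 0.032, the heat shock response at 0.054, DNA replication at 0.049 and p53 targets at 0.033. Hypoxia and glycolysis stood at -0.029, and at -0.072 after quantile normalization, where they were called (adjusted p = 0.011). Oxidative phosphorylation at 0.040, NRF2 targets at 0.054, iron handling at 0.041, epithelial genes at 0.0032, markers of stroma and endothelium at -0.067, or 0.019 with members at background set to their bound, and reference genes at 0.10.

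None of the 23085 genes was called in H2009 by limma over all genes tested (0 genes), while 1466 had an unadjusted p under 0.05, 878 of them lower with wtB2M, against 1154 expected by chance. Adjusted over the list alone, 1 list member passed. The smallest adjusted p of all genes, 0.0607, belonged to CPS1, the urea cycle carbamoyl phosphate synthetase, which was not above background on any H2009 array. CEP295NL was at least 1.68-fold lower, SH2D1A, a lymphocyte signalling adaptor above background on 1 H2009 mock array and no wtB2M array, was lower, LOC100652957 at 0.58, and the probe A_33_P3383084 was at background in both groups. None of these 5 passed (limma adjusted p = 0.581 for the last 4).

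In H2135, wtB2M arrays showed the rise of B2M and falls of weakly expressed transcripts. Of 25 called genes, B2M alone was higher and 24 were lower, 8 of these by at least 2-fold with genes at background set to their bound. GARIN1B, which encodes a Golgi protein that binds RAB2, was at least 8.45-fold lower with wtB2M (limma adjusted p = 0.0210), and LCN15, a lipocalin, at least 2.30-fold lower (limma adjusted p = 0.0210). MTARC2, a mitochondrial molybdenum enzyme, was at least 1.83-fold lower (limma adjusted p = 0.0110). FGL1, a secreted ligand of the inhibitory receptor LAG-3, was at least 1.59-fold lower (limma adjusted p = 0.0355).

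Among the further named genes, FXYD3, a regulator of the sodium pump, was at least 1.53-fold lower, ALDH3B2, an aldehyde dehydrogenase, at least 1.39-fold lower, and PLAGL1, an imprinted zinc finger gene, at least 1.36-fold lower. CEACAM7, a carcinoembryonic antigen family member, fell by 0.91 on the log2 scale with a standard error of 0.13, and 2 of its 3 wtB2M arrays were above background. For MTARC2 and FXYD3 the other probes were lower as well without passing, at -0.72 for MTARC2 and at -1.65 and -0.62 for FXYD3. The remaining 16 lower genes carry names that are only a probe, transcript, locus or open reading frame code, such as LINC00839 and C1orf116.

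These 24 genes shared a low signal. Their median level was -5.03 against -1.26 for all genes, 23 lay below that median, 21 of them were above background on none of the wtB2M arrays of H2135, and none was above background on all 6 H2135 arrays. On H2009 arrays 11 of the 24 were never above background. The filter kept these 11 through H2135 alone, mostly through the mock arrays on which they were high. With no filter on dim probes 12 of the 24 stayed called. The median fitted change of the 24 was -1.89 with a median standard error of 0.24, or -0.65 with genes at background set to their bound, and within the single slide with both H2135 groups the fitted median was -1.54. In 13 of the 24, mock replicate 3, the array with 70.6% of probes above background, held the highest of the mock values. Every H2135 mock array had more probes above background than every H2135 wtB2M array, at least 57.7% against at most 52.1%. Over all genes, 2652 had an unadjusted p under 0.05, 2498 of them lower. limma called 0 genes with the slide as a fixed block, although the 24 kept a median of -1.85 with a median standard error of 0.25, and fewer residual degrees of freedom remained. Normexp background correction left 2 and shrank the median to -0.42 with 0.16, and leaving out mock replicate 2 raised the count to 593.

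**Figure D2:**
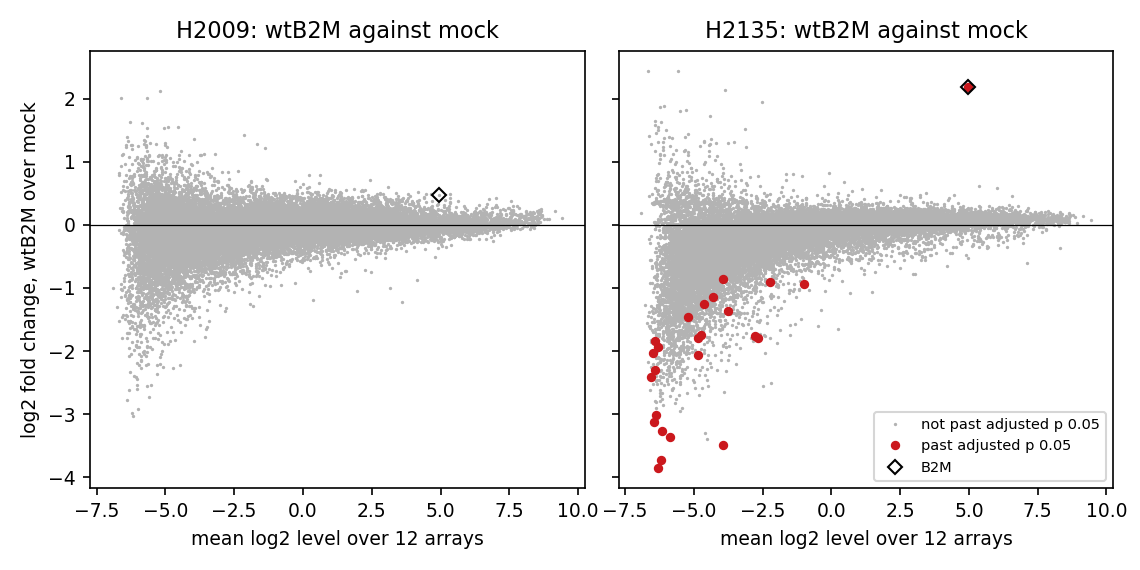
Log2 fold change of wtB2M over mock (vertical axis) against the mean log2 level over the 12 arrays (horizontal axis), 1 point per gene, for H2009 and H2135, with genes past adjusted p 0.05 in red and B2M as a diamond. In H2135 the called genes other than B2M lie among the dim genes, with a median level of -5.03.

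As groups, 8 lists were called in H2135 and each was shifted upwards by a small amount. Oxidative phosphorylation genes were shifted by 0.16 (camera adjusted p = 3.76e-06), with all 29 members above the median of all genes. With an estimated correlation no list was called in H2135, and the adjusted p was 0.550 for each of these 8. In the first list NDUFB5, a complex I subunit, differed by 0.22 and ATP5MC1, of the ATP synthase, by 0.24. G2/M and mitosis genes were shifted by 0.14 (camera adjusted p = 2.33e-05), 29 of 30 above the median of all genes, with PTTG1, the securin, at 0.46 and the kinase AURKA at 0.15. Without H2135 wtB2M replicate 2 these lists stood at 0.089 (adjusted p = 0.00433) and 0.082 (adjusted p = 0.00601), and without mock replicate 3 G2/M stood at 0.071 (adjusted p = 0.0106). The unfolded protein response was shifted by 0.14 (camera adjusted p = 0.00333), with the chaperones HYOU1 at 0.17 and MANF at 0.18. Cholesterol biosynthesis was shifted by 0.13 (camera adjusted p = 0.00342), with INSIG1, a sterol sensor, at 0.33.

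The other called lists in H2135 were reference genes at 0.13 (camera adjusted p = 0.0117), DNA replication at 0.10 (camera adjusted p = 0.0107), MHC class I presentation at 0.11 (camera adjusted p = 0.0259) and immediate-early and MAPK targets at 0.097 (camera adjusted p = 0.0141). These calls ended when single arrays were left out. Without H2135 wtB2M replicate 2 reference genes stood at 0.048 (adjusted p = 0.112) and MHC class I at 0.078 (adjusted p = 0.103), and without mock replicate 2 at 0.067 (adjusted p = 0.120) and 0.10 (adjusted p = 0.118). Without mock replicate 3 DNA replication stood at 0.046 (adjusted p = 0.357) and immediate-early and MAPK targets at 0.090 (adjusted p = 0.0874). MHC class I also lost its call without mock replicate 2 of H2009, at an unchanged 0.11 (adjusted p = 0.0605), since that array enters only the estimate of the spread. In the class I list, the immunoproteasome subunits PSMB8 and PSMB9 stood at 0.29 and 0.16, and NLRC5, the transactivator of class I genes, at -0.33. No member of the 8 lists was called over all genes or adjusted over the list alone. A fixed block for the slide left 3 lists called: G2/M at 0.16 (adjusted p = 8.53e-05), cholesterol at 0.096 (adjusted p = 0.0117) and oxidative phosphorylation at 0.062 (adjusted p = 0.0445). The other 5 fell to shifts of 0.026 for MHC class I to 0.055 for DNA replication. Within the single slide with both groups the shifts were 0.092 for G2/M, 0.13 for cholesterol, 0.027 for oxidative phosphorylation, 0.047 for the unfolded protein response and for reference genes, 0.025 for MHC class I, 0.098 for immediate-early and MAPK targets and 0.0010 for DNA replication. After quantile normalization no list was called in H2135, with shifts from -0.015 for DNA replication and -0.014 for MHC class I to 0.068 for cholesterol.

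The other 16 lists were not called in H2135, with adjusted p from 0.0778 upwards. Markers of blood cells stood at -0.23, or -0.19 with members at background set to their bound, and lung differentiation at -0.17, or -0.066 at the bound. Fitted shifts were -0.30 for stroma and endothelium, -0.24 for cancer-testis antigens, -0.12 for MHC class II presentation, -0.083 for NF-kB targets and -0.072 for mesenchymal and TGF-beta targets. At the bound these shifts stood between 0.012 and 0.046. Members set to 0 there lie above the median of all genes, which was -0.046. The change of sign can therefore come from that rule and shows no rise of these lists. The heat shock response stood at 0.096, NRF2 targets at 0.081, hypoxia and glycolysis at 0.073, p53 targets at 0.060, iron handling at 0.059, the interferon gamma response at 0.048, epithelial genes at 0.040, the type I interferon response at 0.033 and NK cell and checkpoint ligands at 0.031. Adjusted over the list alone, 5 members passed although none did over all genes. They were GBP4, an interferon-induced GTPase, at -1.14 with a standard error of 0.20, IDO1, a tryptophan-degrading enzyme, at -0.84 with 0.19, the leukocyte marker PTPRC at -1.07 with 0.23, the stromal gene DCN at -0.87 with 0.20, and CD3E, a T cell receptor component, at least 2.04-fold lower. Their adjusted p over all genes ran from 0.0652 for GBP4 to 0.170 for CD3E.

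**Figure D3:**
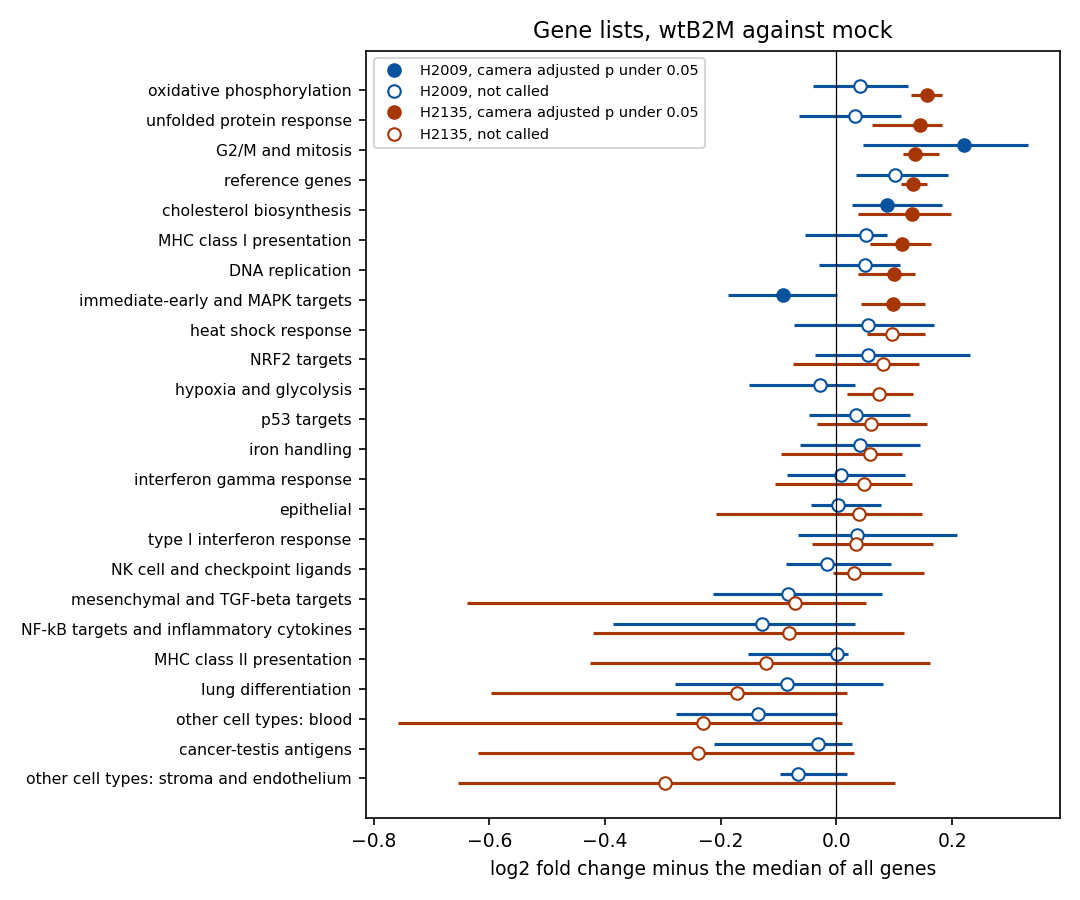
Shift of each gene list between wtB2M and mock: the median log2 fold change of its members minus that of all genes (horizontal axis), with bars over the quartiles of the members, for H2009 in blue and H2135 in red, filled where the camera adjusted p is under 0.05. The G2/M and mitosis list stands at 0.22 in H2009 and 0.14 in H2135, and the immediate-early and MAPK list at -0.093 and 0.097.

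The difference between the lines asks whether the plasmid changed H2135 otherwise than H2009. B2M differed by 1.71 on the log2 scale with a standard error of 0.28, larger in H2135, and did not pass over all genes (limma adjusted p = 0.316). Immediate-early and MAPK targets were shifted by 0.19 towards H2135 (camera adjusted p = 0.000104), oxidative phosphorylation by 0.15 (camera adjusted p = 0.00157) and hypoxia and glycolysis by 0.14 (camera adjusted p = 0.0175). With an estimated correlation none of the 24 lists was called for the difference, and the adjusted p was 0.880 for each of these 3. Among the immediate-early genes EGR2 differed by 0.81, EGR1 by 0.54, JUN by 0.43 and MYC by 0.39. Among hypoxia genes EGLN3, an oxygen-sensing hydroxylase, differed by 0.37 and ADM, a vasoactive peptide gene, by -0.71.

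With the slide as a fixed block the shift of immediate-early and MAPK targets was 0.13 (adjusted p = 0.0200), that of oxidative phosphorylation 0.046 and that of hypoxia and glycolysis 0.032, the last pair with an adjusted p of 0.958. After quantile normalization the shifts were 0.086 (adjusted p = 0.0388), 0.046 (adjusted p = 0.408) and 0.061 (adjusted p = 0.221) in the same order. limma called 0 genes for the difference, and 1141 had an unadjusted p under 0.05 against 1154 expected. The 10 smallest p-values belonged to B2M, GARIN1B, MTARC2, CPS1 and the code-named C1orf116, LOC100652957, A_33_P3221318, XLOC_006751, XLOC_000505 and XLOC_l2_000604, with limma adjusted p from 0.237 to 0.350. LOC100652957 had a fitted difference of -0.82 with a standard error of 0.13. The others except B2M were at background in both groups of at least 1 line or in the wtB2M arrays of H2135.

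Averaged over both lines, B2M came closest to the threshold, at 1.33 on the log2 scale with a standard error of 0.14 (limma adjusted p = 0.0636). limma called 0 genes on average, while 3292 had an unadjusted p under 0.05, 2792 of them lower. MTARC2 and CHRND, a subunit of the acetylcholine receptor, were lower, both at background on the wtB2M arrays of H2135. The code-named A_33_P3221318 and Q6LRY1 were at background in H2009, and these 4 did not pass (limma adjusted p = 0.0776). Adjusted over the list alone, 5 list members passed: the inflammatory cytokine IL32 at -0.72, GBP4 at -0.60, PTPRC at -0.70, and IL6 and DCN, which were lower and at background on the wtB2M arrays of 1 line.

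The lists gave 7 calls for the average, and none with an estimated correlation, where the smallest adjusted p was 0.400. G2/M and mitosis stood at 0.19 (camera adjusted p = 2.94e-08, 29 of 30 members above the median of all genes), with KIF23, a cytokinesis motor, at 0.21 and PTTG1 at 0.30. Cholesterol biosynthesis stood at 0.11 and oxidative phosphorylation at 0.11 (camera adjusted p = 0.000602 each), reference genes at 0.12 (camera adjusted p = 0.00998), the unfolded protein response at 0.088 and DNA replication at 0.074 (camera adjusted p = 0.0329 each). Blood markers stood at -0.23 (camera adjusted p = 0.0466). With the slide as a fixed block G2/M at 0.21 (adjusted p = 1.14e-08), cholesterol at 0.14 (adjusted p = 0.0001) and blood markers at -0.16 (adjusted p = 0.0270) kept their calls, and NF-kB targets at -0.18 gained one (adjusted p = 0.00875). DNA replication at an undiminished 0.077 and oxidative phosphorylation at 0.070 (adjusted p = 0.0541 each), the unfolded protein response at 0.061 (adjusted p = 0.348) and reference genes at 0.056 (adjusted p = 0.562) lost theirs. After quantile normalization only G2/M stayed, at 0.11 (adjusted p = 0.0161), with cholesterol at 0.039 and blood markers at -0.11.

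No gene was called in both lines (0 by limma). At an unadjusted p under 0.05 in both, 14 genes were higher in both lines and 182 lower in both, where independence would give 3.9 and 95, and 13 went opposite ways. Across genes the changes in the lines correlated at 0.279 (Pearson) and 0.297 (Spearman), genes not being independent replicates. The lines share no arrays, but each of the 5 slides held arrays of both.

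The mock arrays show what set the lines apart without the plasmid, and the difference was broad. Some epithelial transcripts of H2009 were above background on none of the H2135 mock arrays. ITGB4, the integrin β4 chain of hemidesmosomes, was at least 1737-fold lower, CDH1, E-cadherin, at least 1533-fold lower, and MIR205HG, the host gene of an epithelial microRNA, at least 489-fold lower in H2135. RB1, the retinoblastoma tumour suppressor, was at least 184-fold higher in H2135 and not above background on any H2009 mock array. NOS2, the inducible nitric oxide synthase, was at least 193-fold higher, ZNF541, a zinc finger gene, at least 208-fold, and the LIMS3-LOC440895 locus at least 183-fold.

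In all, 13689 of the 23085 genes, 59.3%, were called between the mock arrays, 7696 higher and 5993 lower in H2135, and 7215 of them by at least 2-fold with genes at background set to their bound. CRACDL, a relative of an actin capping regulator, had a fitted log2 difference of 9.29 with a standard error of 0.41 and was above background on 1 of the H2009 mock arrays; a second probe of it stood at 2.61 and did not pass (limma adjusted p = 0.0594). SNX3, a sorting nexin, differed by -11.64 with a standard error of 0.63 and was above background on 1 of the H2135 mock arrays; its other probes stood at -10.83 and -1.78. Of the called genes with other probes, 3775, another probe was called the same way in 2690 and the opposite way in 256. On the slides that held mock arrays of both lines, 99.8% and 99.7% of called genes had the same direction as in the pooled fit. These arrays belong to the fit that called the genes, so the shares could hardly be low and do not test for a slide effect.

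Epithelial genes were the most shifted list called between the lines, at -3.12 (camera adjusted p = 2.95e-06), with 16 of 20 members lower in H2135, 2 higher and 17 lower when adjusted over the list alone. With an estimated correlation neither this list nor any other was called, and the smallest adjusted p was 0.438. GRHL2, an epithelial transcription factor, was at least 43.7-fold lower. Mesenchymal and TGF-beta targets were not called as a list at -0.77, with 9 members higher and 13 lower. ZEB1, a repressor of CDH1, was higher by 6.37 on the log2 scale with a standard error of 0.14, while TGFBI, an adhesion protein of the matrix, differed by -9.90 with 0.14 and TWIST1 was at least 17.9-fold lower. In the lung differentiation list, not called at -0.18, the lung lineage factor NKX2-1 was at least 534-fold lower in H2135 and FOXA2 at least 36.3-fold lower, whereas ABCA3, a surfactant lipid transporter, was higher by 3.26 with a standard error of 0.14.

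B2M was 5.31-fold lower in H2135 mock than in H2009 mock arrays, a log2 difference of -2.41 with a standard error of 0.20 (limma adjusted p = 2.21e-06), and stood at -2.27 and -2.25 on the shared slides. MHC class I presentation was shifted by -1.03 (camera adjusted p = 0.0126), with 12 of 21 members lower and 5 higher, or 12 and 6 adjusted over the list alone. HLA-E was 7.58-fold lower, HLA-B 4.85-fold, the peptide transporter subunit TAP1 4.55-fold and HLA-C 3.83-fold. MHC class II presentation was not called as a list at -0.37, with 6 members lower and 3 higher; its master regulator CIITA was at least 7.25-fold lower. NF-kB targets were shifted by -1.32 (camera adjusted p = 8.38e-05), or -1.06 with members at background set to their bound, with 18 of 28 lower, LCN2, a siderophore-binding lipocalin, at least 84.0-fold and IL6 13.1-fold.

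Metabolic and stress lists went different ways between the mock arrays. NRF2 targets were shifted by -1.22 (camera adjusted p = 0.00312, 14 of 21 lower), with NQO1, a quinone reductase, 2.99-fold lower. Cholesterol biosynthesis was shifted by -0.71 (camera adjusted p = 0.000751, 15 of 22 lower), with SQLE, squalene epoxidase, 3.68-fold lower, and hypoxia and glycolysis by -0.43 (camera adjusted p = 0.00894, 13 of 25 lower), with the glucose transporter SLC2A1 9.20-fold lower. Cancer-testis antigens were shifted by -1.56 (camera adjusted p = 0.0283, 7 of 13 lower), with MAGEA4 at least 34.0-fold lower.

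Lists higher in H2135 were immediate-early and MAPK targets at 0.77 (camera adjusted p = 0.00894, 19 of 28 higher), G2/M and mitosis at 0.47 (camera adjusted p = 0.0283, 20 of 30 higher), oxidative phosphorylation at 0.34 (camera adjusted p = 0.0283, 18 of 29 higher) and the heat shock response at 0.35 (camera adjusted p = 0.0356, 9 of 15 higher). SPRY4, a feedback inhibitor of MAPK signalling, was 14.5-fold higher and DUSP4, a MAPK phosphatase, 13.8-fold lower. CYCS, cytochrome c, was 4.14-fold higher and the mitotic kinase CDK1 2.47-fold higher. With the slide as a fixed block all 11 lists kept an adjusted p under 0.05, the highest being 0.0250 for the heat shock response. After quantile normalization G2/M at 0.31 (adjusted p = 0.146), oxidative phosphorylation at 0.23 (0.0993) and the heat shock response at 0.24 (0.0870) lost their calls, and the unfolded protein response at -0.52 gained one (0.0464).

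Of the lists not called between the mock arrays, the type I interferon response stood at -0.17 with 15 members higher and 14 lower. In it IFI27, an interferon-induced mitochondrial protein, was 45.1-fold higher and IFITM1, an antiviral membrane protein, 33.7-fold lower in H2135. The interferon gamma response stood at -0.34, NK cell and checkpoint ligands at -0.31, the unfolded protein response at -0.39, iron handling at -0.40, DNA replication at 0.041, p53 targets at 0.064 and reference genes at 0.15. Markers of blood cells stood at 0.20, with 5 of 15 higher and 1 lower, and markers of stroma and endothelium at -2.50, or -1.24 at the bound, with 4 of 7 lower and 2 higher.

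**Figure D4:**
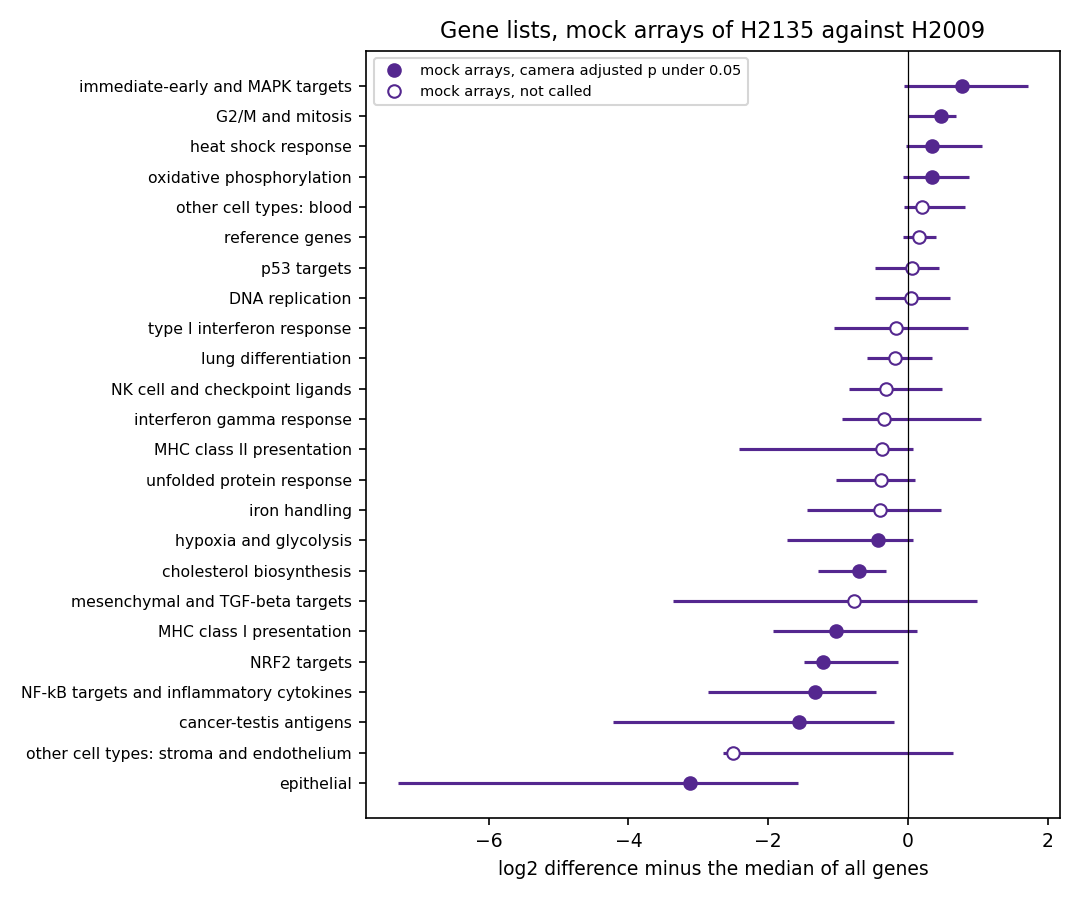
Shift of each gene list between the mock arrays: the median log2 difference of its members, H2135 minus H2009, minus that of all genes (horizontal axis), with bars over the quartiles of the members, filled where the camera adjusted p is under 0.05. Epithelial genes stand at -3.12 and immediate-early and MAPK targets at 0.77.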

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

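The tests of saturation, of added signal, of a single array, of background and of mixed RNA for the called genes were chosen only after the results were seen. Other splits and the fits without each array were chosen beforehand. The tests of signal level, and the reading of left-out arrays for single lists, were aimed at lists already called.

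The change of B2M with wtB2M differed between the lines by 1.71 on the log2 scale, with an unadjusted limma p of 0.000121, which did not pass over all genes (limma adjusted p = 0.316). A probe at its upper limit in H2009 would hide part of a rise there, but 589 genes were brighter than B2M on the H2009 wtB2M arrays and no spot of the probe was saturated, which argues against that. An equal amount of added transcript was not excluded. On the linear scale wtB2M arrays lay above mock arrays by 17.8 ± 5.03 (SE) in H2009, where the rise was not called, and by 31.4 ± 6.39 in H2135. The difference was 13.6 ± 8.14, or 1.68 standard errors. With 3 arrays per group such a test could hardly reject equal amounts, so it does not show that they were equal. If the added amounts were equal, the lower starting level of H2135, 8.55 against 45.5 in units of the array's 75th percentile, would give a larger log2 change there. A difference between the lines in how well the plasmid was taken up or transcribed stays open, untested.

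Gene lists differed between the lines as well: the shift of immediate-early and MAPK targets by 0.19, that of oxidative phosphorylation by 0.15 and that of hypoxia and glycolysis by 0.14, each towards H2135. Immediate-early and MAPK targets went opposite ways, at -0.093 in H2009 and 0.097 in H2135. So did hypoxia and glycolysis, at -0.029 and 0.073, while oxidative phosphorylation stood at 0.040 and 0.16. The adjusted p of each was 0.880 with an estimated correlation. With the slide as a fixed block oxidative phosphorylation at 0.046 and hypoxia and glycolysis at 0.032 lost their calls (adjusted p = 0.958), as they did after quantile normalization at 0.046 and 0.061 (adjusted p = 0.408 and 0.221). Immediate-early and MAPK targets kept theirs at 0.13 with the block and at 0.086 after quantile normalization.

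The 24 genes lower with wtB2M in H2135 are dim. Each H2135 mock array had more probes above background (57.7%, 58.5% and 70.6%) than each H2135 wtB2M array (50.4%, 52.1% and 50.8%). H2135 mock replicate 3 had more than any other array. Without that array their median fitted change was -1.84, against -1.89 with it, and 7 of the 24 genes stayed called. The 24 genes were chosen as lower on these same arrays, and their mock and wtB2M values did not overlap. Their median could therefore hardly shrink much when that array was left out. The comparison cannot decide whether that array is the cause. RNA of H2009 in the H2135 mock arrays would bring its abundant transcripts, but 14 such transcripts rose by a median of 0.00216 of what the falls would need. That need, a median of 14.8% of H2009 RNA, came from the 12 of the 24 genes above background on all 3 H2009 mock arrays. It need not hold for each of these genes. A background difference between the arrays cannot be told apart from the pattern: probes above background on no array gained on the mock arrays 0.177 of the net signal that the 24 genes did, and genes near the floor decide little. A true loss of weak transcripts also stays open, untested.

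The G2/M and mitosis list was shifted upwards with wtB2M in both lines, by 0.22 in H2009 and 0.14 in H2135, and it lost both calls with an estimated correlation (adjusted p 0.925 and 0.550). In H2009 leaving out any of the 12 arrays ended 0 calls, but the H2135 arrays enter only the estimate of the spread there. Without mock replicate 2 the shift fell to 0.050 (camera adjusted p = 0.0155), so that array may carry much of its size. Random lists of matched level, drawn with all arrays, ranged from -0.017 to 0.092, which includes 0.050. The kept calls therefore cannot exclude that array together with the signal level. With all arrays the tables argue against the signal level of the members, since among 10000 random lists of matched level the list lay at percentile 100, and after quantile normalization it kept a shift of 0.19 (adjusted p = 0.00695). Candidate explanations for H2009 that stay open, untested, are an effect of the plasmid on the cell cycle and the growth state at harvest, which the labels do not record.

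In H2135 the signal level may account for the G2/M shift, at percentile 90.9 and with a shift of 0.025 after quantile normalization (adjusted p = 0.725). Leaving out any of the arrays ended 0 calls there too, but the shift fell to 0.071 without mock replicate 3 (adjusted p = 0.0106) and to 0.082 without wtB2M replicate 2 (adjusted p = 0.00601). The level may also account for 6 of the 7 other lists called in H2135, which lay within the range of lists of matched level; only the unfolded protein response, at percentile 98.6, lay above. It may also account for the cholesterol list in H2009, at percentile 93.7 and without a call after quantile normalization (0.046, adjusted p = 0.194).

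The splits of the 6 arrays of a line are too few for a share under 0.05. In H2009 the real split gave 0 genes and the highest other 3, where 10 of 10 are as high by construction, and it gave 3 lists against 7, with 6 of 10 as high. In H2135 the real split gave 25 genes and the highest other 15, so 1 of 10, and 8 lists against 7, also 1 of 10. Between the mock arrays it gave 13689 genes against 3, again 1 of 10. The highest G2/M shift of the other splits was 0.16 in H2009 and 0.15 in H2135. With 100 drawn splits over both lines the real count was 0 for the difference, for the average and for both lines, so all 100 reach it by construction and the count decides nothing; the highest other counts were 408, 408 and 0. The split with 408 genes put H2009 mock replicate 1 with wtB2M replicates 2 and 3 and kept the true H2135 groups, which points to a structure of the arrays whose source was not tested, and its H2009 part gave 3 genes alone. Mock replicate 1 and wtB2M replicate 3 of H2009 share a slide, but the split with 408 genes was not refitted with the slide as a block. With that block the real groups gave 0 genes for the difference and 0 for the average. They gave as many without it, so these counts say nothing about that split.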

How the results depend on the processing

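No alternative was chosen after the results were seen, and the cause of each change below was not tested unless it is given. Between the mock arrays the called genes numbered 10779 to 15312 in the alternatives that kept the threshold, and 7745 with a minimum change of 1 on the log2 scale, which by construction removes smaller changes. There 144 of 144 values of named genes, most of them chosen as the largest differences, kept their direction and call. The B2M difference in H2009 ranged from 0.36 to 0.64 and was never called. In H2135 the B2M rise ranged from 2.01 to 2.64. It lost its call with the slide as a fixed block (2.01, adjusted p = 0.178) and with only the 2 groups of the comparison (2.19, adjusted p = 0.169), where fewer residual degrees of freedom remain; leaving out 1 array gave 2.02 to 2.43, each called, and the lowest adjusted p was 0.000459.

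The 25 genes called in H2135 became 2 with normexp, 15 after quantile normalization, 1 with a filter at all 12 arrays (B2M), 9 with the deposited values, 44 with the slide as a random block, 0 with it as a fixed block, 9 with a variance trend, 698 with array weights and 0 with only the groups of the comparison. The filter at all 12 arrays measured none of the 24 lower genes. Leaving out 1 array gave 8 to 593. Outside a factor of 1.5 were the counts without H2135 mock replicate 2 (593) or 3 (13), without H2135 wtB2M replicate 1 (8), 2 (14) or 3 (56), and without H2009 mock replicate 1 (39) or 2 (15) or wtB2M replicate 1 (16) or 2 (11). All 24 lower genes stayed lower in each setting that measured them, with a median of -0.42 under normexp, -0.45 with the deposited values, -1.16 after quantile normalization, -1.85 with the slide as a fixed block and -1.89 with a variance trend, against -1.89 in the pooled fit. They were chosen as lower on these same arrays, so the kept direction decides little. Of the 24, 1 stayed called under normexp, 4 with the deposited values and 6 after quantile normalization. With a replicate block 8 stayed called, with a variance trend 8, with median centring 12 and with no filter on dim probes 12.

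The 0 genes in H2009 became 1 with the slide as a random block, 1 with array weights and 0 to 2 with 1 array left out. The 0 genes for the difference became 3 with median centring, 2 with array weights and 0 to 63 with 1 array left out (63 without H2135 mock replicate 2). The 0 genes for the average became 1 with normexp, 3 after quantile normalization, 2 with median centring, 1 with the filter at all 12 arrays, 1 with the deposited values, 4 with a replicate block, 1 with a variance trend, 29 with array weights and 0 to 196 with 1 array left out (196 without H2135 mock replicate 2, 117 without H2009 mock replicate 1). Genes called in both lines were 0 throughout. Residuals of mock and wtB2M arrays with the same replicate number correlated at -0.19 to 0.12, with both signs in each line. The labels do not say whether the numbers mark a shared batch, so a pairing of the arrays stays open.

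The 3 lists in H2009 became 5 with array weights, 1 with only the groups of the comparison, 0 with an estimated correlation, 0 with fry and 1 to 4 with 1 array left out (1 without H2009 mock replicate 1 or H2135 mock replicate 2); the G2/M list was called in 25 of 25 settings with a fixed correlation, at 0.050 without H2009 mock replicate 2 and 0.13 with array weights. Over these, the adjusted p of G2/M ran from 3.59e-07 to 0.0155, that of cholesterol from 2.9e-05 to 0.652 and that of immediate-early and MAPK targets from 1.69e-05 to 0.525. The 8 lists in H2135 became 0 after quantile normalization, 0 with the deposited values, 5 with the filter at all 12 arrays, 3 with the slide as a fixed block, 0 with an estimated correlation, 0 with fry and 6 to 11 with 1 array left out. There the adjusted p of G2/M ran from 2.35e-06 to 0.886, that of cholesterol from 0.000654 to 0.886 and that of oxidative phosphorylation from 2.69e-07 to 0.886; the G2/M shift was 0.071 without H2135 mock replicate 3 and 0.082 without wtB2M replicate 2. Reversed shifts were -0.014 for MHC class I presentation and -0.015 for DNA replication after quantile normalization, and -0.016 for DNA replication with the deposited values. With median centring the median of all genes stood at 0.11 in H2009, 0.41 in H2135 and 0.30 between mock arrays, against -0.050, -0.046 and 0.13 with the 75th percentile. Block by scan date was not run. Signal over background limits the falls in H2135, since 21 of 24 genes were above background on no wtB2M array.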

Other observations

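The values in this part were looked up only after the results were seen, and no test was chosen beforehand for them.

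Among the iron genes of the mock arrays, SLC40A1, the iron exporter ferroportin, was 6.69-fold lower in H2135, and STEAP3, a ferrireductase, 2.85-fold lower. CP, ceruloplasmin, was at least 1.85-fold higher. Among ligands read by NK and T cells, ULBP2, a ligand of NKG2D, was 6.30-fold lower in H2135, while NCR3LG1, a ligand of NKp30, was 6.02-fold higher and TNFRSF14, a ligand of BTLA, 4.46-fold higher. In the p53 list PHLDA3 was 5.09-fold lower and the ribonucleotide reductase subunit RRM2B 3.03-fold higher. In the DNA replication list, cyclin E1, CCNE1, was 3.21-fold lower. The interferon gamma targets ICAM1, an adhesion molecule, and SOCS1, a cytokine signalling inhibitor, were 7.70-fold and 2.76-fold higher in H2135, while GBP4 was 2.61-fold lower.

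H2009 mock arrays spread more than the other groups. The median standard deviation of a gene within the group was 0.245, against 0.147 for H2009 wtB2M, 0.157 for H2135 mock and 0.135 for H2135 wtB2M. B2M stood at percentile 96.5 of all genes on H2009 mock arrays, and in H2135 at 86.0 on mock and 95.5 on wtB2M arrays.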
